A study of Gallus gallus with 14 samples.

How the data were processed

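The deposited values were taken as they stand: 1 linear intensity per probe set and array, with all values positive. The mean of each array after trimming 2% at each end was 499.9, so the authors had scaled every array to a common mean. The deposited labels name neither the summarising software nor the scaling. The 9 instrument files deposited with the arrays, whose unit is recorded as other, hold fluidics and scanner settings and no RNA measurement, and they were used only to tell array batches apart. All 9 share 1 hybridization time and 1 scan day, and the 5 arrays without such a file have no stated batch.

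The file holds 38535 probe sets, of which 96 control probe sets were left out. Array medians ran from 83.3 to 145, a ratio of 1.74. The rule fixed before the data were examined called for quantile normalization of log2(intensity + 16) where this ratio exceeds 1.2, and that was the scaling used. The rest of the plan, which covers the filter, the tests, the gene lists and the rule for named genes, was also made before the data were examined. The 40% of probe sets with the lowest mean log2 signal over the 14 arrays were left out (a signal limit of 57.5), which left 23063. The supplied probe table gave a single symbol to 17942 of these, for 10206 genes. Where a gene had several tested probe sets, the one with the highest mean signal stood for it. Called probe sets of 1 gene had opposite signs in 62 of 1668 genes with at least 2 called probe sets for E18 against E7, 2 of 354 for E10 against E7, 0 of 141 for E14 against E10 and 7 of 652 for E18 against E14. The single MKI67 probe set was left out as dim.

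Samples were grouped by age as labelled: 4 arrays at E7, 3 at E10, 3 at E14 and 4 at E18. All 14 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with a moderated F over the 4 ages and moderated 2-sided contrasts for E18 against E7 and the 3 adjacent intervals. P values were adjusted by the Benjamini-Hochberg method over all tested probe sets, and an adjusted p under 0.05 is named a call. The verbs rose, fell and changed are used for calls. Transient profiles were probe sets higher, or lower, at E10 or E14 than at both E7 and E18, with a call in both contrasts. Principal components and array figures were computed on the same values, and figures were drawn with matplotlib 3.10.9.

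The 27 gene lists cover the visual cycle, melanin, tight and adherens junctions, apical microvilli, ion and nutrient transport, phagocytosis, basement membrane, stroma, cartilage, cell division, transcription factors, secreted factors, glycolysis, oxidative phosphorylation, ribosomal proteins, sterol metabolism and oxidative stress, and markers of photoreceptors, other retinal neurons, erythrocytes, endothelium, leukocytes, muscle, lens and neural crest. Each was tested with limma's camera at a preset correlation of 0.01 on 1 probe set per gene, and adjusted over all 108 tests. List counts refer to the genes kept by the filter for dim probe sets. It kept 12 of 25 photoreceptor genes with a probe set, 19 of 30 stromal genes, 19 of 30 ion transport genes and 11 of 22 endothelial genes. As the filter used the mean over all ages, a gene dim at 1 age could pass through its signal at another. Camera was repeated with a correlation estimated per list, adjusted the same way, and fry was run beside it. Named genes were the 12 largest rises and falls for E18 against E7 and the 8 largest for each interval with non-overlapping arrays, 6 peaks and 6 troughs, up to 4 members per list with the smallest adjusted p and the member with the list's largest interval change, and a fixed set with RPE65, TYR, MITF, OTX2, OCLN, TJP1, claudins, SLC2A1 and TOP2A. LRAT, MCM6 and the immediate-early genes of the last part were named after their values were seen.

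The alternatives fixed beforehand were another filter, the deposited scale, median centring, other pseudocounts (1 and 64), no trend, array weights, fits on the ages compared alone, blocks, stricter thresholds and leaving out each array. The fits within and without the shared session, with fluidics stations as a block, and without the arrays that stood apart were chosen after the data were seen. In the session fit E7 had 1 array, which was assumed to vary like the others. The chain from normalization to calls was run on simulated data with known changes. The simulated arrays were drawn around already normalized values, with independent noise and few changed probe sets. They therefore cannot test the correction of scale differences, the effect of batches or a case where many probe sets change. Of the 66 probe sets with a 4-fold change between 53 and 58 were found, and of the 67 with a 1.5-fold change between 12 and 21. Between 2 and 7 unchanged probe sets were called as well.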

Results

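RNA from sheets of retinal pigment epithelium (RPE), the pigmented layer behind the neural retina, was measured on 14 whole-genome chicken arrays. The embryos were at embryonic day 7 (E7, 4 arrays), E10 (3 arrays), E14 (3 arrays) and E18 (4 arrays). Each array held an independent preparation, pooled from 20 to 30 eyes according to the design text. The median deposited signal ran from 83.3 to 145 per array, and the precision of every value below is limited by the 3 or 4 arrays per age. After normalization, 23063 probe sets were tested, and 10206 genes were represented among them. Changes below are log2 differences between age means with the standard error (SE) of the limma fit. Where the mean of an age lay below a log2 signal of 6.2, the limit of the filter for dim probe sets, the size of a change depends on the pseudocount, and its value and rank are no exact measure.

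Age ordered the arrays on the first principal component, which held 42.1% of the variance, from E7 at the low end through E10 and E14 to E18. On the second component, with 15.7% of the variance, E7 replicates 1 and 2 and E18 replicates 2 and 3 lay between 38.28 and 54.91, and the other arrays between -36.33 and 12.36. The same 4 arrays had the lowest ratios of 3' to 5' ACTB signal, a measure of RNA integrity and labelling, at 1.18 to 1.30, against at least 1.36 in the rest. The 9 arrays with an instrument file shared 1 hybridization and scan session, named the shared session below, and whether the others belonged to it is not known. Within this session the fluidics stations followed age, with the E7 array on station 1 and the E18 arrays on station 3. For E18 against E7, age and station therefore cannot be told apart within the session. The 5 arrays without such a file were E7 replicates 1, 2 and 3 and E18 replicates 2 and 3. Blood content also differed within ages: signal for HBA1, an alpha globin, was 11.95 and 12.01 (log2) in E7 replicates 1 and 2 and 8.90 and 7.59 in replicates 3 and 4, while at E18 it was 14.89 and 14.83 in replicates 1 and 4 and 9.84 and 9.67 in replicates 2 and 3.

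**Figure D1:**
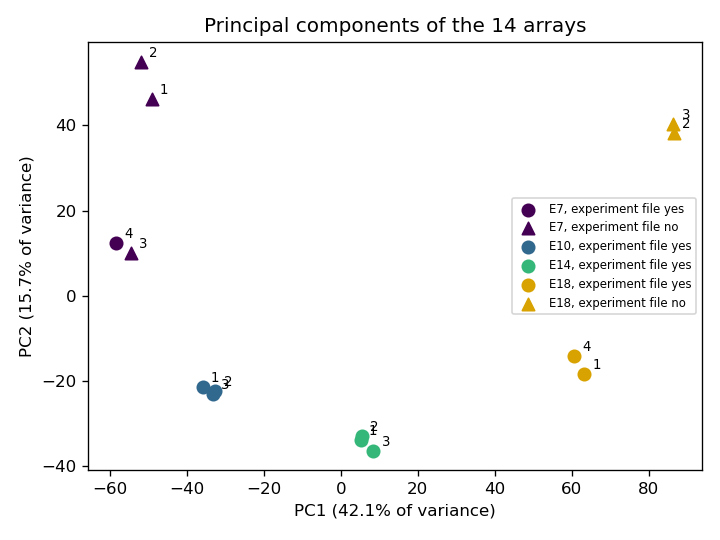
Each point is 1 array on the first (x axis) and second (y axis) principal component of the normalized log2 signals, with the share of variance in the axis labels, coloured by age, numbered by replicate and drawn as a circle or a triangle for arrays with or without an instrument file. E18 arrays lie at 60.53 or above on the first component and E7 arrays at -49.15 or below, while 2 arrays of each of these ages lie above 38 on the second.

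Across the 4 ages, 9708 of 23063 probe sets (42.1%) changed with age by limma's moderated F test, and they stood for 5638 named genes. The 9 arrays of the shared session gave 8892 probe sets.

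The comparison of E18 with E7 shows how the tissue differed between the youngest and oldest embryos (4 arrays each). Of all 10206 genes 21.6% rose and 26.7% fell, and the counts of each list below are to be read beside these shares. The visual cycle and retinoid list, the enzymes and carriers that renew the visual chromophore, had 11 of 13 measured genes rising and none falling, also 11 when adjusted over the list alone. RPE65, the retinoid isomerase, went from 9.30 ± 0.39 (SD, n = 4) to 15.02 ± 0.03 (SD, n = 4), a 53.0-fold rise. The carrier TTR rose by 5.94 ± 0.08 (SE), the retinol-binding protein receptor STRA6 by 5.49 ± 0.15 and the carotenoid-cleaving enzyme BCO1 by 2.40 ± 0.05. LRAT, the enzyme that esterifies retinol, rose by 3.80 ± 0.39 and was singled out after its values were seen. The list was called by camera (adjusted p = 1.12e-08, and adjusted p = 0.00512 with an estimated correlation). Within the shared session its median change was 2.04, and within the other 5 arrays 1.88.

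Genes for the barrier and the cell surface moved in both directions. Of 23 tight junction genes, 10 rose and 5 fell, the same counts when adjusted over the list alone, and the list was not called (adjusted p = 0.0917). The strand proteins CLDN1, CLDN20, CLDN2 and CLDN5 rose by 5.58 ± 0.21, 5.45 ± 0.36, 3.87 ± 0.19 and 1.34 ± 0.08. OCLN rose by 0.77 ± 0.15. The scaffold gene TJP1 fell by 0.44 ± 0.16, but within the shared session its change was 0.13 and not called. The TJP1 call also ended without E7 replicate 1 (-0.34), E7 replicate 2 (-0.32), E14 replicate 2 (-0.44), E18 replicate 1 (-0.45), E18 replicate 2 (-0.42), E18 replicate 3 (-0.45) or E18 replicate 4 (-0.46). In the adherens junction and polarity list 3 of 26 rose and 9 fell, the same when adjusted over the list alone (list adjusted p = 0.536), with falls of the cadherins CDH2 (-2.12 ± 0.18) and CDH3 (-1.23 ± 0.13) and of the polarity gene PARD6G (2.83-fold lower). CDC42 rose by 0.42 ± 0.04. After median centring 4 of the adherens junction genes rose and 5 fell. Among 16 genes of apical microvilli and cytoskeleton, 5 rose and 5 fell (6 and 5 adjusted over the list alone, list adjusted p = 0.84), ESPN, an actin-bundling protein, rising by 4.25 ± 0.13, PLS1 rising by 1.27 ± 0.22 and TPM1 falling by 1.44 ± 0.06. That list's median was -0.00956 while its mean, 0.346, and its test pointed up. The median was 0.00184 on the deposited scale, with 5 rising and 3 falling, and 0.217 after median centring, with 5 rising and 2 falling.

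Transport genes also split. Of 19 ion and water transport genes 7 rose and 4 fell, with the same counts adjusted over the list alone (list adjusted p = 0.429): the carbonic anhydrase gene CA14 rose by 4.46 ± 0.38, the bicarbonate transporter SLC4A7 by 1.63 ± 0.11 and the chloride transporter CLCN3 by 0.95 ± 0.08, and the sodium-potassium-chloride cotransporter SLC12A2 fell by 1.56 ± 0.15. After median centring 7 of these genes rose and 1 fell. Of 22 nutrient and metabolite transport genes 11 rose and 7 fell, likewise over the list alone (list adjusted p = 0.108), with rises of the dicarboxylate transporter SLC13A3 (3.34 ± 0.08), SLC39A12 (1.71 ± 0.09), the glycine transporter SLC6A9 (1.69 ± 0.10) and the glucose transporter SLC2A1 (0.57 ± 0.05). Of 26 phagocytosis and lysosome genes 10 rose and 4 fell, likewise over the list alone (list adjusted p = 0.108), including CD36 (2.43 ± 0.17), SCARB2 (2.26 ± 0.17) and the protease CTSD (0.61 ± 0.05). This list was called on the deposited scale (adjusted p = 0.0124) and after median centring (adjusted p = 0.0149), where 12 rose and 1 fell.

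Pigment genes moved in both directions. Of 20 melanin and melanosome genes 4 rose and 8 fell (5 and 9 adjusted over the list alone), and the list was not called (adjusted p = 0.712). TYR, the rate-limiting enzyme of melanin synthesis, fell by 0.21 ± 0.04 from a mean of 14.76, SLC24A5 fell by 0.76 ± 0.11 and OCA2 by 0.56 ± 0.08, and MREG rose by 1.41 ± 0.19 (0.855 within the shared session). With each array centred on its median, the list's median turned from -0.125 to 0.0948, the TYR change to 0.03, and 2 genes rose and 2 fell. On the deposited scale 3 rose and 5 fell.

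Genes of cell division fell. In the DNA replication and cell division list 29 of 42 fell and 2 rose (29 and 3 adjusted over the list alone), with a median of -1.53. The microtubule regulator STMN1 fell by 3.19 ± 0.19, as did the mitotic kinase gene CDK1 (-2.87 ± 0.24), TYMS (-2.54 ± 0.20) and TOP2A (-1.80 ± 0.18). The list was called (adjusted p = 5.83e-06), and not called with an estimated correlation (adjusted p = 0.0626). Cytosolic ribosomal protein genes also fell: 52 of 58 fell and none rose (53 adjusted over the list alone), with a median of -0.587 (adjusted p = 7.64e-21, and adjusted p = 0.00643 with an estimated correlation). RPL35A fell by 1.51 ± 0.06 and RPL12 by 1.23 ± 0.06. The medians within the shared session and within the other arrays were -0.583 and -0.6, while after median centring 22 fell with a median of -0.324. The ratio of 3' to 5' EEF1A signal moved alongside, from 1.35 ± 0.0157 (SD, n = 4) at E7 to 1.54 ± 0.0577 (SD, n = 4) at E18.

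Among metabolic genes, more rose than fell for respiration and antioxidant defence. Of 74 oxidative phosphorylation genes 35 rose and 4 fell, likewise over the list alone, with a median change of 0.137 (adjusted p = 3.3e-04, and adjusted p = 0.444 with an estimated correlation). The median was 0.33 on the deposited scale, with 45 rising and 2 falling, and 0.545 after median centring, with 42 rising and none falling. COX6A1 rose by 0.74 ± 0.05 and SDHD by 0.81 ± 0.07. Of 29 oxidative stress genes 18 rose and 2 fell (22 and 3 adjusted over the list alone), with an adjusted p = 2.48e-05, and adjusted p = 0.00638 with an estimated correlation. Extracellular superoxide dismutase, SOD3, rose by 5.53 ± 0.27, SQSTM1 by 2.15 ± 0.14 and GPX4 by 0.74 ± 0.04, and GSTA2 fell by 0.96 ± 0.07. Glycolysis (4 of 16 rose, 7 fell, likewise over the list alone, list adjusted p = 0.82) and sterol and fatty acid metabolism (12 of 26 rose, 9 fell, likewise over the list alone, list adjusted p = 0.269) were not called. The glycolysis median was -0.0765 and its mean 0.025, and the lean to falls turned with the scaling: on the deposited scale 5 rose and 5 fell (median 0.0484), and after median centring 4 rose and 2 fell (median 0.263). After median centring 12 sterol genes rose and 5 fell. PDK4, which restrains pyruvate oxidation, rose by 2.12 ± 0.14 and ENO1 fell by 0.77 ± 0.06. The sterol synthesis genes SQLE and HMGCS1 rose by 2.50 ± 0.16 and 2.09 ± 0.15, while the fatty acid binding protein gene FABP5 fell by 1.83 ± 0.13.

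Matrix and regulatory genes were divided. Of 28 basement membrane genes 17 fell and 6 rose, likewise over the list alone, without a call for the list (adjusted p = 0.135): COL4A4 (2.14 ± 0.15), TIMP3 (1.39 ± 0.09) and NID1 (2.3-fold) rose, and LAMB1 (-2.11 ± 0.13) and ITGB1 (-1.15 ± 0.06) fell. After median centring 8 fell and 6 rose, and the median went from -0.67 to -0.363. Among 19 stromal genes 5 rose and 6 fell, likewise over the list alone (list adjusted p = 0.84). COL6A1 (5.43 ± 0.25) and COL6A2 (3.25 ± 0.22) rose, and ELN (-4.42 ± 0.21) and COL12A1 (-3.53 ± 0.23) fell. The E7 mean of COL6A1 lay below 6.2, and its rise was 5.9 and 4.56 with pseudocounts of 1 and 64. Of 9 cartilage genes 1 rose, the link protein gene HAPLN1 (4.06 ± 0.21), and 3 fell, among them COL2A1 (-3.22 ± 0.23) and LECT1 (-4.54 ± 0.47, and -2.86 within the shared session), likewise over the list alone (list adjusted p = 0.479). In the optic vesicle and RPE transcription factor list 2 of 16 rose and 7 fell, likewise over the list alone (list adjusted p = 0.562). PAX6 fell by 1.51 ± 0.13, SOX4 by 1.43 ± 0.21, LHX2 by 1.00 ± 0.15 and MITF by 0.65 ± 0.12, SIX3 rose by 1.08 ± 0.19, and OTX2 rose by 0.16 ± 0.05. Within the shared session SOX4 and LHX2 had smaller changes (-0.938 and -0.481) and SIX3 a larger one (1.64). The OTX2 call ended within either array set, without E7 replicate 3 (0.13) and without E18 replicate 2 (0.14), and the MITF call after median centring (-0.35). Of 40 secreted factor and signalling genes 13 rose and 10 fell (14 and 11 adjusted over the list alone, list adjusted p = 0.562), with a median of 0.0285, or -0.0117 on the deposited scale, and a mean of -0.155. The heparin-binding growth factor gene MDK fell by 6.68 ± 0.21, PDGFA fell by 2.67 ± 0.13 and IGFBP2 rose by 1.76 ± 0.10.

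Markers of other cells moved as well. Of 12 photoreceptor genes 4 rose and none fell, likewise over the list alone (list adjusted p = 0.143), with PDE6G up by 2.57 ± 0.27 and GNAT2 by 3.09 ± 0.40 (1.78 within the shared session). Of 17 other retinal neuron and glia genes 2 rose and 5 fell (3 and 5 over the list alone, list adjusted p = 0.84, median 0.117, or -0.148 on the deposited scale, mean -0.113), with ELAVL4 down (-3.11 ± 0.19) and PROX1 up (2.90 ± 0.21). The embryonic globin genes HBZ and HBE fell by 2.65 ± 0.53 and 1.22 ± 0.36, calls that ended within the shared session, where the changes were -1.01 and -0.27. The HBE call also ended without E7 replicate 1 (-0.92) or E7 replicate 2 (-0.99). CA13 rose by 2.80 ± 0.75, with signals of 9.78 and 9.81 in E18 replicates 1 and 4 and 6.05 and 6.12 in replicates 2 and 3. The E7 means of GNAT2 and CA13 and the E18 mean of HBZ lay below 6.2. With pseudocounts of 1 and 64 the changes were 3.89 and 2.21 for GNAT2, 3.62 and 1.95 for CA13 and -3.31 and -1.84 for HBZ. Of 6 erythrocyte genes 1 rose and 2 fell, likewise over the list alone (list adjusted p = 0.856). Within the shared session 3 rose and none fell with a median of 2.67, and of the 4 genes measured in the other arrays none rose and 2 fell with a median of -1.43. Of 13 macrophage and leukocyte genes 4 rose and 1 fell, likewise over the list alone (list adjusted p = 0.301), with CSF1R up by 1.04 ± 0.10 and CD74 by 1.21 ± 0.14. In the endothelial list (11 genes, adjusted p = 0.755) 1 gene rose and 1 fell, in the striated muscle list (9 genes, adjusted p = 0.268) 3 rose and 1 fell, in the lens list (8 genes, adjusted p = 0.562) 2 rose, and in the neural crest list (5 genes, adjusted p = 0.741) PMP22 fell by 1.86 ± 0.21. These counts were the same when adjusted over each list alone.

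The named genes with the largest rises at this pseudocount were ABI3 (7.15 ± 0.22), the steroid dehydrogenase gene HSD11B1B (6.57 ± 0.23), the tetraspanin gene CD82 (6.51 ± 0.16), the mitochondrial creatine kinase gene CKMT1B (6.41 ± 0.27), TTR, the secreted Wnt inhibitor WIF1 (5.86 ± 0.24), RPE65, RGCCL (5.59 ± 0.36), CLDN1, SOD3, STRA6 and CLDN20. The E7 means of ABI3, HSD11B1B, WIF1, SOD3 and CLDN20 lay below 6.2: the rise of ABI3 was 8.10 with a pseudocount of 1 and 5.85 with 64, and that of CLDN20 6.08 and 4.40. The TTR rise, with an E7 mean of 8.93, was 5.98 and 5.80. Besides MDK, large falls were those of the matrix glycoprotein gene EMILIN3 (-6.64 ± 0.26), the glycosyltransferase gene GALNT7 (-5.69 ± 0.22), CPZ (-5.67 ± 0.23), the netrin receptor gene UNC5C (-5.36 ± 0.30), LECT1, ELN, CMTM8 (-4.36 ± 0.19), TMEM200A (-4.13 ± 0.27), the mitotic kinesin gene KIF15 (-4.13 ± 0.26), the mitotic kinase gene PBK (-4.12 ± 0.48) and SERPINE3 (-4.10 ± 0.09). The E18 means of MDK, EMILIN3, CPZ, UNC5C and PBK lay below 6.2, and with pseudocounts of 1 and 64 the changes were -7.25 and -5.71 for MDK, -7.38 and -5.53 for EMILIN3 and -7.22 and -4.14 for CPZ. In total 9388 probe sets passed the test, 4245 higher and 5143 lower at E18, of which 1707 and 1769 changed at least 2-fold. A fit on the arrays of these 2 ages alone gave 7822. The shared session alone gave 7617 and the other 5 arrays 7866. The share that was higher, 45.2%, depended on the scaling: it was 35.2% on the deposited scale, where the median change of all tested probe sets was -0.201, and 54.8% after median centring.

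**Figure D2:**
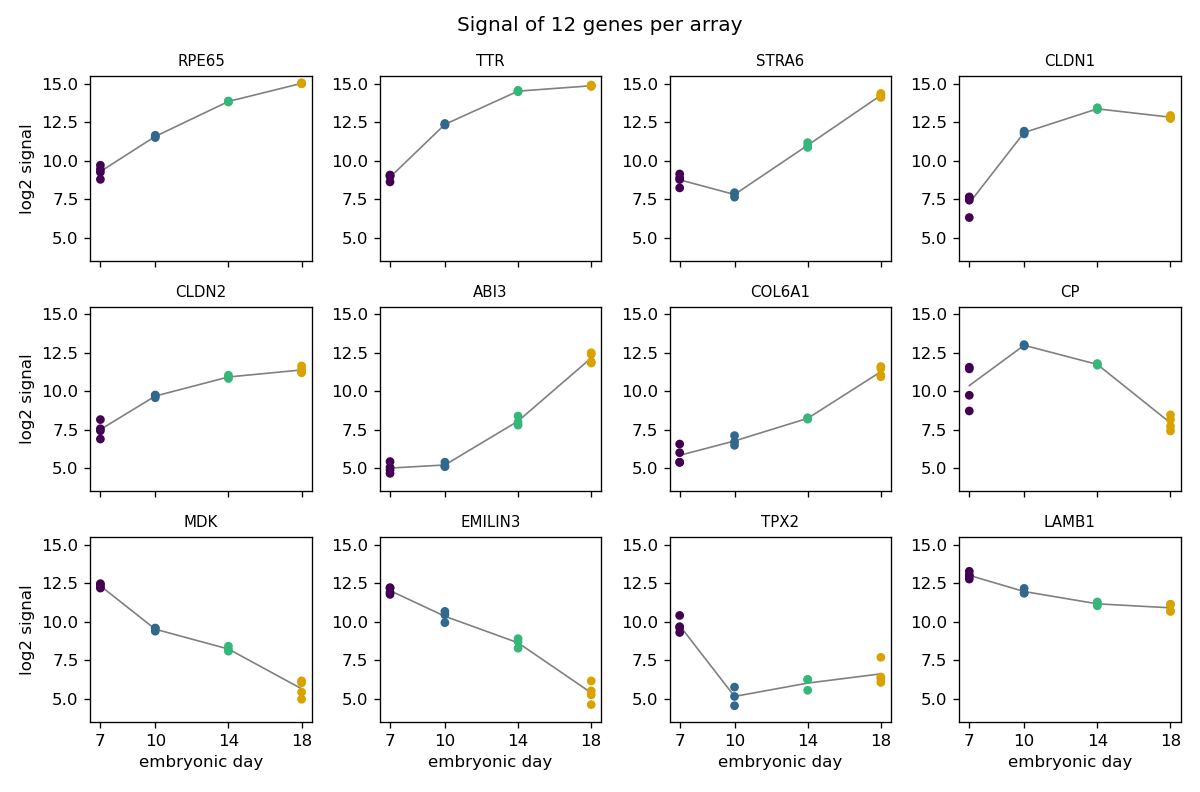
Each point is the normalized log2 signal (y axis) of 1 array at its embryonic day (x axis) for 12 named genes, coloured by age, and the grey line joins the age means. RPE65 has means of 9.30, 11.58, 13.85 and 15.02, CLDN1 is at 7.25 at E7 and at 11.83 at E10, and CP is at 12.99 at E10 and at 7.95 at E18.

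The comparison of E10 with E7 (3 and 4 arrays) covers the first interval. Of all 10206 genes 8.79% rose and 8.08% fell. Cell division genes were lower at E10: 27 of the 42 fell and 1, MCM6, named after its values were seen, rose (32 and 1 adjusted over the list alone), with a median of -1.29 (adjusted p = 1.12e-13, and adjusted p = 0.00603 with an estimated correlation). The spindle factor gene TPX2 fell by 4.60 ± 0.40, as did the ribonucleotide reductase gene RRM2 (-3.70 ± 0.37), CDCA3 (-3.64 ± 0.27), the mitotic activator gene CDC20 (-2.96 ± 0.43) and the mitotic kinase gene PLK1 (-2.87 ± 0.28). DCK2 (-3.92 ± 0.44), UNC5C (-3.24 ± 0.32) and the cohesin gene SMC1B (-3.09 ± 0.50) were the other large falls. The E10 means of TPX2, RRM2, CDC20, DCK2 and SMC1B lay below 6.2, and with pseudocounts of 1 and 64 TPX2 changed by -5.49 and -3.44 and RRM2 by -4.34 and -2.77. Within the shared session, where 33 of the list's genes were measured and E7 had 1 array, 14 fell and 1 rose with a median of -1.07.

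CLDN1 rose by 4.58 ± 0.23, or 23.9-fold, and CLDN2 and CLDN5 rose by 2.17 ± 0.21 and 1.71 ± 0.08. CLDN20 changed by 0.26 ± 0.39 and was not called. In all, 4 of 23 tight junction genes rose and none fell (5 and 1 adjusted over the list alone, list adjusted p = 0.106). The other large rises were the immediate-early transcription factor gene EGR1 (4.28 ± 0.16), the tyrosine-degrading enzyme gene TAT (4.19 ± 0.63), the amino acid transporter gene SLC6A20 (4.05 ± 0.27), TTR (3.43 ± 0.09), COL6A6 (3.10 ± 0.44), the cytokine signalling inhibitor gene SOCS3 (3.06 ± 0.13) and REEP6 (3.06 ± 0.28). The E7 means of TAT and COL6A6 lay below 6.2, and their changes with pseudocounts of 1 and 64 were 4.98 and 3.17, and 3.91 and 2.23. RPE65 rose by 2.28 ± 0.14 while STRA6 fell by 0.95 ± 0.16, and the visual cycle list, with 5 of 13 up and 2 down (6 and 2 adjusted over the list alone), had an adjusted p = 0.00778, and adjusted p = 0.106 with an estimated correlation.

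Of 28 basement membrane genes 9 rose and 2 fell, 10 and 2 adjusted over the list alone. Camera called the list as higher (adjusted p = 0.00928), but not with an estimated correlation (adjusted p = 0.501). COL4A4 (1.66 ± 0.16), NID1 (1.09 ± 0.06) and TIMP3 (0.89 ± 0.09) rose, while LAMB1 fell by 1.05 ± 0.14. The list lost its call with the presence of an instrument file as a block (adjusted p = 0.18), and after median centring 5 rose and 1 fell. Of 58 ribosomal protein genes 14 fell and none rose (25 fell over the list alone, median -0.107, adjusted p = 2.46e-05, and adjusted p = 0.229 with an estimated correlation), but 6 fell on the deposited scale and none after median centring. Of 74 oxidative phosphorylation genes 13 fell and 2 rose, 15 and 4 over the list alone, with a median of -0.0715. Camera called the list as lower (adjusted p = 0.0219), but not with an estimated correlation (adjusted p = 0.596). The list call ended on the deposited scale (adjusted p = 0.427) and after median centring (adjusted p = 0.701). It also ended without E7 replicate 3, E7 replicate 4 or E10 replicate 1 (adjusted p = 0.0806, 0.073 and 0.107). Among transporters the transferrin receptor gene TFRC fell by 1.95 ± 0.11 and the zinc transporter family gene SLC39A12 rose by 1.48 ± 0.09. CYR61 rose by 1.17 ± 0.14. Among genes listed as markers of other cells, EDNRB (2.31 ± 0.20) and CSF1R (0.85 ± 0.11) rose. SOX10 (-1.23 ± 0.09), HBE (-1.82 ± 0.39, and -1.06 and not called within the shared session) and ELAVL4 (-0.97 ± 0.21) fell. The macrophage and leukocyte list (2 of 13 rose, none fell, likewise over the list alone, adjusted p = 0.392) was not called. Nor was the neural crest list (1 of 5 rose, 1 fell, 1 and 3 over the list alone, adjusted p = 0.458). SOX10 signal was 12.4 to 12.6 at E7 and EDNRB signal 12.6 to 12.8 at E10, and whether other cells contributed to these changes was not tested. The photoreceptor list had no called gene of 12, also over the list alone (list adjusted p = 0.987).

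In total 2866 probe sets passed, 1579 higher and 1287 lower at E10, and 476 and 288 of them changed at least 2-fold. The shared session gave 2736, of which 1730 were also called in all arrays, median centring gave 1045 with 67.7% higher against 55.1%, and the count was 1888 without E10 replicate 3. The lower count was 824 without E10 replicate 1 and 827 without E10 replicate 3. E7 replicate 4, the only E7 array with an instrument file, was processed at the same fluidics station as E10 replicate 1, and their residuals correlated at 0.407, the highest of all pairs. With stations as a block 1877 probe sets passed, 1400 of them among the 2866.

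The comparison of E14 with E10 (3 arrays each, all from the shared session) covers the middle interval. Of all 10206 genes 4.70% rose and 2.79% fell. Retinoid genes rose again: 8 of 13 rose and none fell (12 adjusted over the list alone), with a median of 0.85 (adjusted p = 5.96e-14, and adjusted p = 0.00186 with an estimated correlation). STRA6 rose by 3.20 ± 0.17, RPE65 by 2.27 ± 0.15, TTR by 2.16 ± 0.10 and BCO1 by 0.87 ± 0.06. Of 29 oxidative stress genes 9 rose and none fell (12 adjusted over the list alone). The list was called by camera (adjusted p = 1.27e-06, and adjusted p = 0.00512 with an estimated correlation). The haem-degrading enzyme gene HMOX1 rose by 3.17 ± 0.29, the autophagy receptor gene SQSTM1 by 2.07 ± 0.16, SOD3 by 1.58 ± 0.31 and GPX4 by 0.53 ± 0.05. Over the same interval HBA1 signal went from a mean of 8.48 to 13.11 (4.63 ± 1.32, not called in the 14 arrays), and the erythrocyte list, not called in the 14 arrays (adjusted p = 0.112), was called within the shared session (adjusted p = 0.00192).

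Of 74 oxidative phosphorylation genes 15 rose and none fell (19 adjusted over the list alone), with a median of 0.165 (adjusted p = 1.3e-07, and adjusted p = 0.229 with an estimated correlation). After median centring 1 of them rose and the list's median was 0.45. Of 28 basement membrane genes 8 fell and none rose (10 adjusted over the list alone, median -0.252), among them LAMB1 (-0.80 ± 0.15) and ITGB1 (-0.50 ± 0.07). Camera called the list as lower (adjusted p = 1.06e-04), but not with an estimated correlation (adjusted p = 0.274). After median centring, which put the median change of all probe sets at 0.155, none of these genes was called and the list's median was 0.0301. The ribosomal protein list was lower, with a median of -0.106 and 4 of 58 genes falling (10 adjusted over the list alone, adjusted p = 5.54e-09, and adjusted p = 0.0807 with an estimated correlation), and this list call ended after median centring (adjusted p = 0.728), where the median was 0.157.

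Large rises were those of the secreted chaperone gene CLU (3.85 ± 0.33), the chemokine gene CXCL14 (3.38 ± 0.45), STRA6, HMOX1, OSGIN1 (2.99 ± 0.33), ABI3 (2.85 ± 0.25), FAM222A (2.81 ± 0.73) and the calcium-binding protein gene S100A6 (2.67 ± 0.61). The E10 means of CLU, CXCL14, ABI3, FAM222A and S100A6 lay below 6.2, and with pseudocounts of 1 and 64 the rises were 4.62 and 2.78 for CLU, 3.95 and 2.46 for CXCL14 and 3.47 and 1.66 for S100A6. At E18, CLU, CXCL14, HMOX1, OSGIN1, FAM222A and S100A6 were higher in replicates 1 and 4 than in 2 and 3, as HBA1 was. FAM222A signal was 8.61 and 8.19 against 5.55 and 5.14. STRA6 and ABI3 were lower in replicates 1 and 4. Whether blood content or another difference between preparations contributed to the rises from E10 to E14 was not tested. Large falls were those of GALNT7 (-3.56 ± 0.25), SPON2 (-2.15 ± 0.43), the protease family gene PRSS35 (-2.04 ± 0.35, with an E14 mean below 6.2, and -1.32 with a pseudocount of 64), CPZ (-1.89 ± 0.26), the matricellular gene CCN3 (-1.87 ± 0.19), CFAP69 (-1.82 ± 0.50), the p53 regulator gene MDM2 (-1.78 ± 0.21) and EMILIN3 (-1.72 ± 0.30). Leaving out 1 array ended the call of FAM222A in 5 cases (E10 replicates 1, 2 and 3 with 2.80, 3.05 and 2.55, and E14 replicates 1 and 2 with 2.95 and 2.90) and that of S100A6 in 4 (E10 replicates 1 and 3 with 2.67 and 2.66, and E14 replicates 2 and 3 with 2.59 and 2.65). The CFAP69 call ended without any of E7 replicates 1, 2 and 3 (-1.81 each), E10 replicates 1, 2 and 3 (-1.82, -1.86 and -1.78) and E14 replicates 1 and 3 (-1.99 and -1.26). CLDN1 and CLDN2 rose further, by 1.54 ± 0.24 and 1.24 ± 0.22, as did ESPN (2.02 ± 0.16), CA14 (1.84 ± 0.44), LDHA (1.95 ± 0.32) and the leukocyte gene LAPTM5 (2.10 ± 0.39). PDE6G and GNAT2 rose by 1.31 ± 0.32 and 1.79 ± 0.47, and the neuronal gene STMN2 by 1.60 ± 0.39, a call that ended without any 1 of the E10 arrays (1.57, 1.68 and 1.56) or E14 arrays (1.61, 1.56 and 1.61). The tight junction (3 of 23 rose, 4 rose and 1 fell over the list alone, adjusted p = 0.301), cell division (2 of 42 fell, none after median centring, 3 over the list alone, adjusted p = 0.4) and photoreceptor (3 of 12 rose, likewise over the list alone, adjusted p = 0.108) lists were not called.

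In total 1337 probe sets passed, 763 higher and 574 lower at E14, and 262 and 153 of them changed at least 2-fold. The shared session alone, whose fit leaves out the arrays that stood apart at E7 and E18, gave 3647, and these held 1326 of the 1337. Fits on the arrays of the ages compared alone gave 3533 for this interval, 2410 for E10 against E7 and 4129 for E18 against E14. For E18 against E7 such a fit gave 7822, fewer than the 9388 of the 14 arrays. The low count of the middle interval thus depends on the spread shared over all 14 arrays, and it is no measure of fewer changes. After median centring 680 passed and 83.8% of them were higher, against 57.1%. The count fell by more than 1.5 times without E10 replicate 1 (790), E10 replicate 3 (836), E14 replicate 1 (788), E14 replicate 2 (773) or E14 replicate 3 (766), each of which left 2 arrays at 1 of the ages. The higher count was 468, 455, 437 and 459 without E10 replicate 1 and E14 replicates 1, 2 and 3, and the lower count 322, 351, 309, 333, 336 and 307 without E10 replicates 1, 2 and 3 and E14 replicates 1, 2 and 3.

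The comparison of E18 with E14 (4 and 3 arrays) covers the last interval. Of all 10206 genes 9.74% rose and 15.17% fell. Visual cycle genes rose further, 9 of 13 with 2 falling, likewise over the list alone (median 0.355, adjusted p = 5.83e-06, and adjusted p = 0.00954 with an estimated correlation). STRA6 rose by 3.25 ± 0.16, LRAT by 2.39 ± 0.42 and RPE65 by 1.18 ± 0.14, while the retinol-binding protein gene RBP4 fell by 2.38 ± 0.40. Ribosomal protein genes fell, 48 of 58 with none rising (50 and 1 adjusted over the list alone), with a median of -0.383 (adjusted p = 7.23e-23, and adjusted p = 0.00603 with an estimated correlation). Within the shared session 48 fell and the median was -0.347. On the deposited scale 29 fell and after median centring 8. RPS12 fell by 1.05 ± 0.09, RPL12 by 0.76 ± 0.06 and RPL35A by 0.72 ± 0.06.

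CLDN20 rose by 3.88 ± 0.39 and CLDN5 fell by 0.36 ± 0.08, while CLDN1 (-0.54 ± 0.23) and CLDN2 (0.46 ± 0.21) were not called. The tight junction list, with 3 of 23 up and 3 down, likewise over the list alone, was not called (adjusted p = 0.862), its median at -0.164 and its mean at 0.0865. Of 22 nutrient transport genes 7 rose and 4 fell (10 and 5 adjusted over the list alone, adjusted p = 0.0326, and adjusted p = 0.274 with an estimated correlation), with rises of SLC13A3 (1.24 ± 0.09) and SLC39A12 (0.39 ± 0.09). Leaving out E14 replicate 3, E18 replicate 1 or E18 replicate 4 ended that call (adjusted p = 0.0515, 0.0546 and 0.078), as did median centring (adjusted p = 0.204), where 3 rose and 4 fell. Of 74 oxidative phosphorylation genes 19 rose and 2 fell (23 and 2 over the list alone, median 0.107). Camera called the list (adjusted p = 1.5e-05), but not with an estimated correlation (adjusted p = 0.291). NDUFS3 rose by 0.84 ± 0.16 (0.535 within the shared session). After median centring 2 of these genes rose and none fell, with a median of 0.094. Oxidative stress genes (7 of 29 rose, 3 fell, likewise over the list alone, adjusted p = 0.0401, and adjusted p = 0.114 with an estimated correlation) included a rise of SOD3 (1.90 ± 0.29) and a fall of HMOX1 (-1.24 ± 0.27, and -0.707 within the shared session). Leaving out E14 replicate 2 ended that list's call (adjusted p = 0.0572).

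Of 28 basement membrane genes 12 fell and 2 rose (12 and 3 over the list alone), with ITGB1 down by 0.55 ± 0.07 and TIMP3 up by 0.28 ± 0.09. Camera called the list as lower (adjusted p = 0.044), but not with an estimated correlation (adjusted p = 0.596). Leaving out any of E7 replicates 1, 3 and 4, E10 replicate 1 and E18 replicate 2 ended the call (adjusted p = 0.0518, 0.0565, 0.052, 0.0511 and 0.0736). Collagen genes parted, COL6A1 and COL6A2 rising by 3.03 ± 0.27 and 2.22 ± 0.24 and COL11A1 falling by 3.17 ± 0.33, and the stromal list (3 of 19 rose, 7 fell, 3 and 8 over the list alone, adjusted p = 0.562) and cartilage list (1 of 9 rose, 4 fell, likewise over the list alone, adjusted p = 0.282) were not called. The stromal median was 0.098, or -0.0111 after median centring, and its mean -0.207. MDK fell by 2.58 ± 0.23 and CYR61 by 3.04 ± 0.14. Of the other retinal neuron genes 1 rose and 5 of 17 fell (1 and 6 over the list alone, adjusted p = 0.323), among them SNAP25 (-1.36 ± 0.23) and STMN2 (-1.82 ± 0.37), with -0.884 and -1.10 within the shared session, while PDE6G rose by 1.48 ± 0.30.

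Large rises were those of NTL (4.70 ± 0.29), CKMT1B (4.66 ± 0.29), the scaffold gene SLC9A3R2 (4.38 ± 0.26), the dopamine receptor gene DRD4 (4.33 ± 0.24), GCH1 (4.10 ± 0.44), which starts tetrahydrobiopterin synthesis, ABI3 (4.10 ± 0.24), the haem-binding protein gene SOUL (4.01 ± 0.20) and CDR2 (3.90 ± 0.23). Large falls were those of the copper-binding ferroxidase gene CP (-3.80 ± 0.49), MXRA5 (-3.73 ± 0.45), the glutamate receptor subunit gene GRIN3A (-3.52 ± 0.42), WFDC1 (-3.33 ± 0.27), the efflux transporter gene ABCB1 (-3.31 ± 0.27), CHODL (-3.28 ± 0.35), EMILIN3 (-3.25 ± 0.28) and COL11A1. The E18 means of CHODL and EMILIN3 lay below 6.2, and their changes with pseudocounts of 1 and 64 were -3.92 and -2.41, and -3.94 and -2.29. In total 4501 probe sets passed, 1917 higher and 2584 lower at E18, and 678 and 781 of them changed at least 2-fold. The lower count was 1688 without E14 replicate 1 and 1713 without E14 replicate 2. The shared session gave 4195, of which 3353 were also called in all arrays. After median centring, which put the median change of all probe sets at -0.109, 2809 passed. Of these 999 were higher and 1810 lower, or 35.6% higher against 42.6%.

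**Figure D3:**
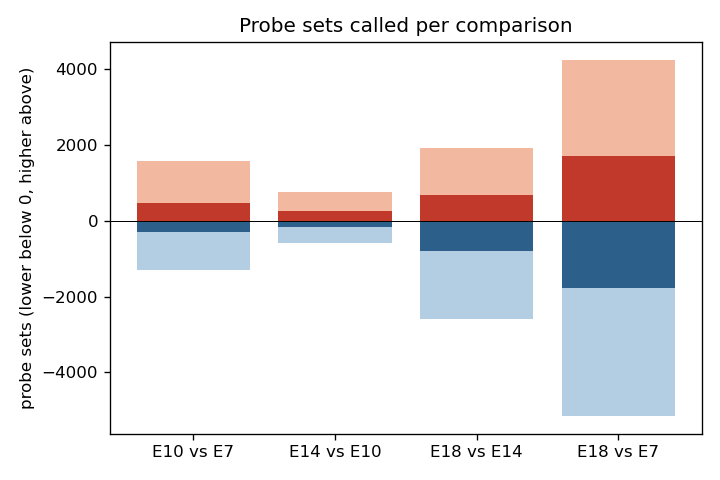
Bars give the number of probe sets called higher (above 0) and lower (below 0) at the later age (y axis) in each comparison (x axis), with the dark part changed at least 2-fold. E18 against E7 has 4245 higher and 5143 lower, and of the adjacent intervals E14 to E18 has the most calls, 4501.

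Among the 9388 probe sets that differed between E18 and E7, the largest of the 3 steps was the last for 4633 (49.4%), the first for 2791 (29.7%) and the middle one for 1964 (20.9%). The intervals span different numbers of days and share arrays, and these shares were not tested against each other.

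Some genes peaked or dipped in between. At E10 or E14, 691 probe sets were higher than at both E7 and E18 and 400 were lower than at both. The age named for a gene below is the middle age that lay further outside both E7 and E18. A difference between E10 and E14 was not required, and some profiles were close to level between them. The E10 and E14 means were 9.63 and 9.95 for TAT, 9.99 and 9.70 for MGP and 12.04 and 11.82 for ACOD1L. CP was highest at E10, by 2.62 ± 0.49 over E7 and with a change of -5.04 ± 0.49 to E18. TAT (4.51 ± 0.63 over E7 and -2.54 ± 0.63 to E18) and RBP4 (4.27 ± 0.40 and -2.38 ± 0.40) peaked at E14. The mineralization inhibitor gene MGP (2.49 ± 0.18 and -3.37 ± 0.18), ACOD1L (2.49 ± 0.26 and -3.20 ± 0.26) and the Wnt agonist gene RSPO3 (2.46 ± 0.57 and -2.54 ± 0.57) peaked at E10. Troughs included the mitotic genes KIF4B (-2.78 ± 0.38 and 2.92 ± 0.38, at E14) and DLGAP5 (-2.09 ± 0.30 and 2.57 ± 0.30, at E10), CA10 (-2.36 ± 0.18 and 1.90 ± 0.18), the serine synthesis gene PSPH (-1.69 ± 0.26 and 2.77 ± 0.26) and JPH3 (-1.79 ± 0.48 and 1.60 ± 0.48) at E10, and TMEM27 (-1.71 ± 0.28 and 1.94 ± 0.28) at E14. Within the shared session the changes of TAT and RSPO3 to E18 were smaller (-1.14 ± 0.16 and -1.33 ± 0.25), as was that of CP from E7 (1.54 ± 0.11). JPH3 was not tested there, and the other named profiles were within 1.5 times of these values. The shared session gave 948 such profiles, and median centring 578.

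**Figure D4:**
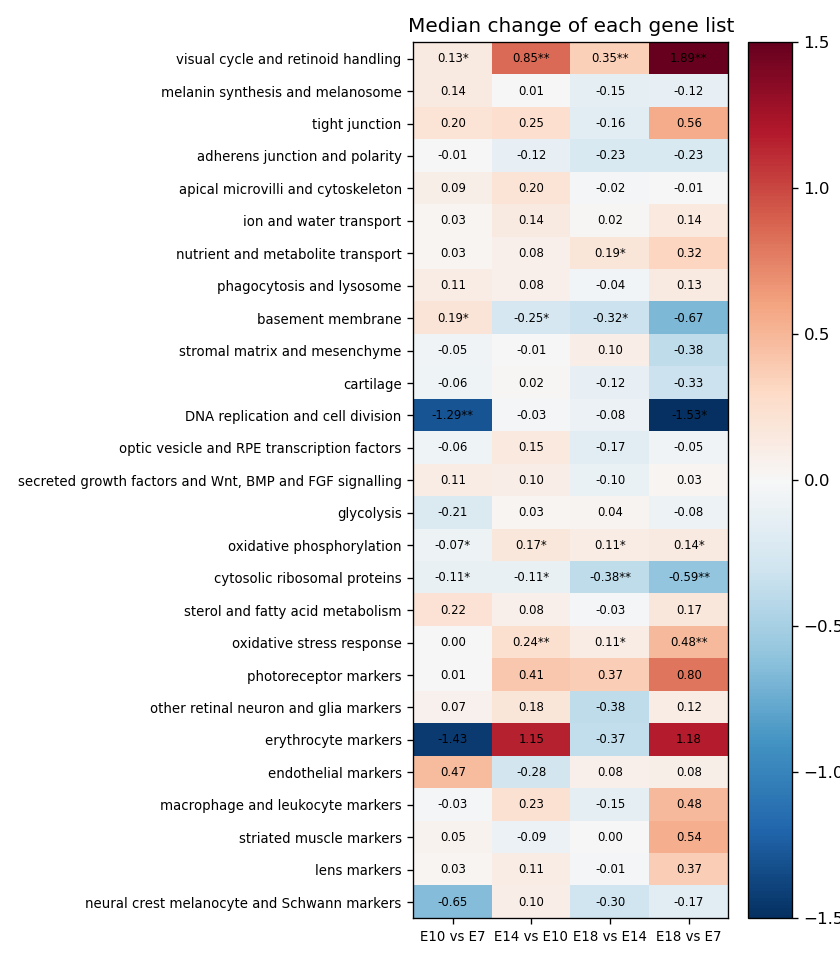
Colour and number give the median log2 change of each of the 27 gene lists (y axis) in each comparison (x axis), with 1 asterisk where camera called the list and 2 where the call also held with an estimated correlation. The visual cycle list has 1.89 for E18 against E7, the cell division list -1.29 for E10 against E7 and the ribosomal list -0.383 for E18 against E14.

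Of 108 list tests 21 passed: 5 for E18 against E7, 5 for E10 against E7, 5 for E14 against E10 and 6 for E18 against E14. With an estimated correlation 3, 1, 2 and 2 of them passed. These were the visual cycle, ribosomal and oxidative stress lists for E18 against E7, cell division for E10 against E7, visual cycle and oxidative stress for E14 against E10, and visual cycle and ribosomal for E18 against E14. At the preset correlation, random regroupings of the same arrays gave a median of 12 lists past the threshold.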

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

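The tests of why 4 arrays stood apart and the test of retinal carry-over were chosen only after those results were seen.

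At E7 or E18, an array lay far from the other 3 of its age, by the gap to its nearest neighbour over the whole range, in 18 of 446 sets of values, and chance gives about 1 in 20. E7 replicate 4 accounted for 7 of them. It was lowest on the third principal component (0.868), for the mean of the ribosomal list (0.912, at 14.43 against 14.46) and for HSD11B1B (0.856), CXCL14 (0.893), SLC9A3R2 (0.88) and PROX1 (0.945), and highest for CRYAB (0.887). E7 replicate 3 was highest for the striated muscle list (0.853). E7 replicate 2 was lowest for CLDN1 (0.84, at 6.309 against 7.434) and highest for CDC20 (0.853), and E7 replicate 1 was highest for COL12A1 (0.867). E18 replicate 2 was highest for the oxidative stress list (0.889, at 11.86 against 11.85) and for ESAM (0.901), and lowest for MDM2 (0.86). E18 replicate 1 was highest for CPZ (0.843), E18 replicate 4 was highest for SLC16A1 (0.914), and E18 replicate 3 was lowest for CFAP69 (0.861) and ERG (0.862).

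E7 replicates 1 and 2 and E18 replicates 2 and 3 stood apart on the second principal component. Of 9 bacterial hybridization controls, added in fixed amounts, 7 read higher in these arrays at both ages, so hybridization or the amount of labelled RNA may be a source of the difference. The differences within E7 and within E18 correlated at 0.296 over probe sets, against at most 0.0832 for the other pairings, just short of the bound of 0.3 set for a shared difference, and 2 of 3 ratios for RNA quality were lower at both ages, so these explanations stay open. HBA1 also parted these arrays, but higher at E7 and lower at E18. No biological explanation was tested, since the labels name none.

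The ribosomal protein list was lower at E18 than at E14. Of 10000 random lists of matched signal 0 had a median as low as -0.383, and the lowest was -0.234, so the list fell more than other genes of like signal. The lists were drawn gene by gene after quantile normalization, which evens out a general loss of bright signal. The test therefore cannot decide on such a loss, and the number of falling genes depended on the scaling, as given above. Within 1 session the list was still called, with a median of -0.347, which argues against a difference between sessions as the whole cause. A change of the ribosomal genes with age may be put forward as a hypothesis, found and tested on the same data. Other differences between preparations of the 2 ages, such as the higher EEF1A ratio at E18, were not tested as a cause.

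PDE6G and GNAT2, genes of photoreceptors, rose from E7 to E18. The lowest change of the 2 genes in the array sets with and without an instrument file was 1.78, and both were called in both sets. The set with files had 1 E7 array, on another fluidics station than its E18 arrays, and the batches of the other set are unknown. These sets therefore cannot exclude a difference between sessions or stations. Neural retina carried over with the sheets may contribute: the other retinal neuron genes had a median change of 0.117 with an SD of 1.29, against 0.799 for the photoreceptor genes, and this spread keeps the explanation open. Expression in the RPE itself with age was not tested.

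Calls were also counted in other splits of the same arrays. Such splits mix ages within a group, which raises the spread, so they cannot exclude chance. The real grouping gave the most calls for any change with age (9708, highest other 2084, 1 of 100 regroupings as large). It also did for E18 against E7 (9388, highest other 830, 1 of 35). The split with 830 parted the 4 arrays that stood apart from the rest. For E10 against E7 the real grouping again gave the most (2866, highest other 1669, 1 of 35). That other split set E7 replicates 1, 2 and 3, which have no instrument file, against the rest. The same holds for E18 against E14 (4501, highest other 3432, 1 of 35), where the other split grouped E18 replicate 1 with the E14 arrays. For transient profiles another regrouping gave more than the real one (1091, highest other 1220, 2 of 100 as large). For E14 against E10 the 10 splits are too few for a share under 0.05 (1337, highest other 0, 1 as large). For the number of gene lists past the threshold chance cannot be excluded (21, highest other 24, 6 of 100 as large). The median of the other regroupings was 12 lists.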

How the results depend on the processing

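The tests with the session, the fluidics stations or the 4 arrays that stood apart were chosen only after the data were seen. No call shared with an alternative had the opposite sign. Counts beyond 1.5 times the reported one were as follows, and the cause was not tested unless given. A 2-fold minimum, stricter by construction, gave 3476 for E18 against E7, 764 for E10 against E7, 415 for E14 against E10, 1459 for E18 against E14 and 301 transient profiles. Adjusted p under 0.01, also stricter, gave 1584, 665 and 2615 for the 3 intervals and 535 transient profiles. Median centring gave 1045, 680, 2809 and 578. Array weights gave 4700 for E10 against E7, 3736 for E14 against E10 and 1706 transient profiles. Stations as a block gave 1877 for E10 against E7, 2891 for E18 against E14 and 501 transient profiles. For E14 against E10, fits on the ages compared alone gave 3533, the instrument file as a block 2025, the shared session 3647, a block for the 4 arrays 2686 and leaving these out 3341. Of gene lists 8 passed with an estimated correlation and 53 with fry, which does not compare with other genes. Leaving out 1 array gave 8826 to 9981 for any change, 8564 to 9364 for E18 against E7, 1888 to 3266 for E10 against E7, 766 to 1472 for E14 against E10, 3073 to 5174 for E18 against E14, 846 to 1253 transient profiles and 19 to 22 lists. Of 4289 values of named genes with 1 array left out, 4180 kept their side of the threshold, 90 lost a call and 19 gained one. Reversed, with no cause tested, were TYR for E18 against E7 after median centring (0.03), TJP1 (0.13) and RSPO3 (1.18) in the shared session, RSPO3 without the 4 arrays (1.08), HBA1 (-2.24), CRYBB2 (-0.12) and the erythrocyte list (adjusted p = 0.0203) in those 4 arrays alone, and the erythrocyte list for E18 against E14 in the shared session (adjusted p = 0.00663).

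The replicate numbers mark no stated pairing: residuals of arrays with the same number correlated between -0.229 and 0.154, and over 0.1 in 2 of 19 pairs. With replicate numbers as a block the counts were 9784 for any change, 9292, 2911, 1220 and 4790 for the comparisons in the order above, 1262 transient profiles and 21 lists. Without the filter for dim probe sets 38439 were tested, and E14 against E10 gave 1118. Whether low signal or the larger number of tests lowered this count was not tested.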

Other observations

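The immediate-early genes below were chosen after EGR1 and SOCS3 were seen, and the bounds for their test were set before its result.

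Between adjacent ages, some lists that were not called held single genes that changed. In the neural crest list SOX10 changed by -1.23 ± 0.09 from E7 to E10 and 0.94 ± 0.09 from E14 to E18, and EDNRB, an endothelin receptor gene, by 2.31 ± 0.20 and -1.46 ± 0.20 (list adjusted p = 0.458 and 0.989). The troponin gene TNNT3 rose by 2.24 ± 0.35 from E14 to E18 (muscle list adjusted p = 0.674). Of 20 melanin genes 4 rose and none fell from E7 to E10 (5 over the list alone, adjusted p = 0.0909), but none rose on the deposited scale or after median centring, and from E14 to E18 2 rose and 6 fell, likewise over the list alone (adjusted p = 0.275), with 1 and 2 after median centring.

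A hypothesis was that the rise of EGR1 and SOCS3 from E7 to E10 may reflect an immediate-early response to dissection. CYR61, an immediate-early gene that rose by 1.17 ± 0.14, was left out of the test together with these 2 genes. The 21 genes left had a median change of 0.168, 8 rose and 3 fell, and camera gave p = 0.0954 (p = 0.0977 with an estimated correlation). ATF3 and BTG2 rose by 0.958 and 0.858, and DUSP4 and DUSP1 fell by 1.45 and 1.05. The median lay below the 0.5 set for such a response, but more genes rose than fell, so the hypothesis was neither borne out nor excluded.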
